A study of Mus musculus with 16 samples.

How the data were processed

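The data were log2 expression values of 16 arrays, as deposited by the authors in a table of 35556 probe sets. The submitters' processing notes name RMA, which corrects the background, normalizes arrays by quantiles and summarizes probes, and Affymetrix Expression Console 1.2, without saying which step each was used for. Whether all 16 arrays were normalized in the same run, and on which days they were processed, was not given in the sources used here. Per the labels' protocols, total RNA was extracted with RNeasy Mini or Micro kits and amplified with the Ovation PicoSL WTA System V2, a whole-transcriptome amplification for small amounts of RNA, before biotin labelling. Amplification of little RNA can add spread between arrays, and after quantile normalization levels are relative, so that a change in the total RNA per cell is not seen. Values lay between 2.423 and 14.167 and array medians between 5.85 and 6.02. No file gave a detection call or background, so dim probe sets could only be left out by their level. The number of arrays limits the precision.

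The design text and the labels give 4 groups: iPSC-derived neurons differentiated with WNT1 and DKK3 (5 biological replicates), iPSC-derived control neurons (5 biological replicates), and primary neurons at E13.5 and at E14.5 (3 technical replicates each). Technical arrays were averaged to 1 sample per stage, and the median SD between arrays over genes was 0.195 in treated, 0.189 in control, 0.228 in E13.5 and 0.215 in E14.5 arrays. Whether the biological replicates came from separate cultures of 1 or of several iPSC lines was not given in the sources used here, so p-values measure the spread between these samples. No 2 arrays held identical values.

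Probe sets were named through the platform's probe table, which lists 23410 of them, 21789 with 1 gene symbol and 1621 with several. A further 12146 probe sets are not listed there and stayed unnamed. Symbols of 21698 probe sets were brought up to date through their Entrez IDs with a RefSeq gene table of the assembly GRCm38.p6, used for names only. The genome build behind the probe table was not given in the sources used here, and no coordinates are given. For the 999 genes with more than 1 probe set, the one with the highest mean was used, and probe sets with several symbols were left out, which gave 19938 genes.

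Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited log2 values, with Benjamini-Hochberg adjustment and a threshold of 0.05. Treated against control used the 10 iPSC-derived arrays with 8 residual degrees of freedom before moderation. The comparisons with primary neurons used 12 samples in 3 groups (control, treated, primary) with 9 residual degrees of freedom, because the primary group holds only 2 samples. E14.5 against E13.5 had no test: a gene counted as different where the means differed by at least 1 on the log2 scale and the 3 arrays of the stages did not overlap. Similarity to primary neurons was the Pearson correlation across genes of each iPSC-derived array with the primary mean, compared by an exact two-sided permutation test of 252 assignments. The shift toward primary neurons was measured with different controls choosing the genes and measuring the shift, over 10 splits.

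The tests, the alternatives and 33 lists with 641 members, of which 593 were measured, were fixed before the data were examined: pathways of dopaminergic identity and subtypes, Wnt signalling, neuronal maturation, proliferation and metabolism, and markers of other cell types that a sort for Pitx3-GFP could hold. They were tested with limma's camera at a preset correlation of 0.01 between genes and again with an estimated correlation, and their members were also counted with the adjustment over the list alone. Muscle and lens genes are among the markers because both tissues can express Pitx3. Lists overlap: Slc17a6 and Slc32a1 stand in a dopaminergic subtype list and in a list of other neurons, Slc1a3 in the progenitor and astrocyte lists, and Krt18 and Ttr in the endoderm list while Ttr is also made by the choroid plexus. For lists in E14.5 against E13.5, the median was set against 10000 random lists matched on size and mean expression. A further 3 lists (trophoblast, choroid plexus, interferon-stimulated genes) were added after seeing the data and are reported with the additional observations.

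The genes named in the text followed a rule fixed at the same time: the 8 genes per direction with the largest difference among those past the threshold, or, where too few passed, those with the smallest unadjusted p, said not to pass; 14 measured genes named in every comparison (Dkk3, Wnt1, Pitx3, Th, Slc6a3, Slc18a2, Nr4a2, Foxa2, En1, Sox6, Otx2, Calb1, Aldh1a1 and Axin2); and the 3 members of each list with the largest difference. Predicted genes, small RNAs and olfactory, vomeronasal, histone and immune receptor genes were counted and not named. Genes named outside this rule (Maoa, Maob, Qdpr, Nanog, Stmn2, Col1a1, Prl7a1, Mir17 and members of the added lists) were chosen after their values were seen. Pitx3 is the reporter locus of the sort, so its level is bound up with how cells were chosen.

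The steps were tested on simulated data made from the real arrays' means and spreads with 50 genes changed by each known amount. Noise was drawn independently for each gene and array, so spread that real arrays share was absent. For treated against control, 46% of genes changed by 0.5 on the log2 scale were recovered, 82% at 1, 98% at 2 and 100% at 3, with 10 unchanged genes called. For control against primary neurons the shares were 26%, 74%, 98% and 98%, with 9 unchanged genes called. For E14.5 against E13.5 they were 0%, 36%, 100% and 100%, with 59 unchanged genes called. The alternatives were the replicate number as a block, other samples in the fit, trend and robust eBayes, quantile normalization or centring of the deposited values, filters on dim genes, the mean of all probe sets of a gene, other thresholds, either stage alone as the primary sample, the 16 arrays with the sample as a random block, other measures of similarity, and leaving out each replicate in turn. The samples numbered 5 were also left out together, a choice made after seeing the data.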

Results

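Gene expression was measured on 16 Affymetrix gene arrays of RNA from mouse cells labelled as midbrain dopaminergic neurons. These neurons supply dopamine to the forebrain and degenerate in Parkinson's disease. For the iPSC-derived samples the word neurons follows the labels, and most of these arrays had low levels of dopaminergic genes, as given below. All cells carried green fluorescent protein (GFP) at the locus of Pitx3, a transcription factor of these neurons, and, per the design text, were collected by fluorescence-activated sorting for GFP; the sample labels name the sort only for primary cells. Neurons on 10 arrays had been differentiated from induced pluripotent stem cells (iPSCs). For 5 biological replicates the culture held recombinant human WNT1, a secreted Wnt ligand, and DKK3, a secreted protein of the Dickkopf family, and for 5 control replicates it did not. The other 6 arrays carried RNA of primary neurons from the ventral midbrain of mouse embryos at embryonic day E13.5 or E14.5. The labels call the 3 arrays of each stage technical replicates, so each stage is 1 sample. Levels are log2 values after RMA normalization, and the medians of the arrays lay between 5.85 and 6.02. The number of arrays sets the precision. Across genes, which are not independent replicates, the correlation was 0.951 to 0.991 between treated arrays, 0.959 to 0.989 between control arrays and 0.813 to 0.869 between iPSC-derived and primary arrays.

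The first comparison asked whether neurons differentiated with WNT1 and DKK3 differed from control neurons, the study's interest being dopaminergic neurons of the substantia nigra. Th, which encodes tyrosine hydroxylase, the rate-limiting enzyme of dopamine synthesis, had a log2 level of 6.36 ± 1.62 (SD, n = 5) in treated and 6.33 ± 1.26 (n = 5) in control neurons. The dopamine transporter gene Slc6a3 had 5.79 ± 1.73 in treated and 5.75 ± 1.51 in control neurons, and Nr4a2, a transcription factor needed for the dopaminergic transmitter phenotype, 7.47 ± 0.95 and 7.40 ± 0.71. None of these differences exceeded the spread between replicates, and no gene passed the threshold in either direction. The log2 difference was 0.02 for Th, with a 95% interval from -1.71 to 1.75, and 0.03 for Slc6a3, with an interval from -1.90 to 1.97. In this fit, which does not use the replicate number, changes of over 3-fold in these genes were not excluded with all arrays. Th on treated and control arrays of equal number was at 5.93 and 6.17, 5.29 and 5.745, 5.79 and 5.34, 5.56 and 5.90, and 9.22 and 8.52. No such difference reached 3-fold, but the labels do not say that equal numbers mark pairs. These wide intervals came from the arrays numbered 5, with Th at 9.22 on treated and 8.52 on control array 5. Without both, a choice made after seeing the data, Th was at 5.64 ± 0.28 (SD, n = 4) in treated and 5.79 ± 0.35 in control neurons, a difference of -0.15 (-0.58 to 0.28), and Slc6a3 differed by -0.07 (-0.31 to 0.17). Slc6a3 was then at 5.02 and 5.08. The group means of both genes lay below the array medians and far below the primary levels of 11.2 and 8.93, although Th exceeded the median on some single arrays. These intervals compare low levels and say little about cells that express the genes. On these arrays the pluripotency gene Nanog was at least 8.42, against 6.18 in primary neurons. With all arrays, the interval was narrower for Pitx3, at 0.03 (-0.28 to 0.34), and for Sox6, a marker of substantia nigra neurons, at 0.01 (-0.35 to 0.37). That of Otx2, a marker of the ventral tegmental area, was also narrower, at -0.14 (-0.57 to 0.29). On the arrays not numbered 5, where Th was low, Sox6 was at 7.10 in treated and 7.07 in control neurons. Otx2 was at 8.16 and 8.425 there, and Pitx3 at 5.88 and 5.82, near the array medians. These levels need not come from dopaminergic neurons, so the narrower intervals say little about such cells. Axin2, a feedback target of Wnt/beta-catenin signalling, differed by -0.13 (-0.46 to 0.21), the mouse gene Dkk3 by 0.08 (-0.34 to 0.50) and Wnt1 by -0.05 (-0.24 to 0.14). Without the arrays numbered 5, the Wnt1 mean was 4.07 in both groups. This lies below the lower quartile of each array (4.32 or more), so the Wnt1 values may be background. The differences of Slc18a2, the vesicular monoamine transporter gene, at 0.04, of Foxa2 at 0.14, of En1 at 0.04, of Calb1 at -0.02 and of Aldh1a1 at -0.07 did not pass either.

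**Figure D1:**
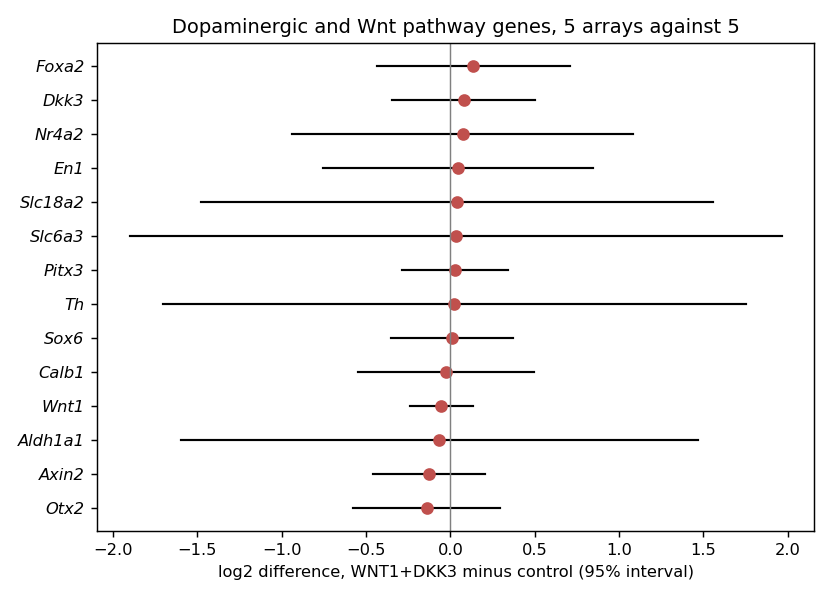
Log2 difference between iPSC-derived neurons differentiated with WNT1 and DKK3 and control neurons (points, 5 arrays against 5) with its 95% interval (lines) for 14 dopaminergic and Wnt pathway genes. Every interval holds 0, and the interval is widest for Slc6a3 (-1.90 to 1.97) and narrowest for Wnt1 (-0.24 to 0.14). Wnt1 had low levels that may be background.

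With limma, 0 genes were higher and 0 lower among 19938 genes, the smallest adjusted p was 0.753, and 300 genes had an unadjusted p under 0.05 where chance alone gives 996.9. For 97.1% of the genes the 95% interval lay within a 2-fold difference in either direction. The genes with the smallest unadjusted p that were higher in treated neurons, none of which passed, were Ivns1abp (log2 difference 0.33), Sbpl (0.38), Cchcr1 (0.29), Fam24a (0.29), Ptchd1 (0.38), Atp8b5 (0.22), Zfyve27 (0.29) and Alpk3 (0.32). Those lower, also not passing, were Eif2ak3 (-0.36), Stoml3 (-0.35), Pycrl (-0.29), Caml (-0.31), Cldn24 (-0.46), Cd160 (-0.28), Tmem100 (-0.38) and Ccdc112 (-0.39). In simulated data with changes of known size and 5 arrays against 5, 46% of genes changed by 0.5 on the log2 scale were recovered, 82% of those changed by 1 and 98% of those changed by 2. The simulated noise was independent between arrays, so spread shared by the arrays numbered 5 or by equal numbers was absent. These shares are for randomly drawn genes and do not apply to Th (SE 0.79) and Slc6a3 (SE 0.88). The median SE over genes was 0.12. With the replicate number added to the fit as a block, limma gave 1 gene higher, Mir17, and 0 lower. An unadjusted p under 0.05 was then reached by 834 genes. The labels do not say whether equal numbers mark pairs. Deviations of treated and control arrays of equal number correlated across genes at 0.44 to 0.80 for numbers 2 to 5, and at 0.045 for number 1. Where equal numbers share a source, the fit without the block counts that shared spread as noise and can miss genes. The low count of 300 genes therefore does not show that treatment changed nothing.

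Among 33 gene lists, 2 passed as lists although none of their members passed alone. Of 28 skeletal and cardiac muscle genes, 0 were higher or lower, also when adjusted over the list alone, but the list as a whole was higher in treated neurons (median 0.14, camera adjusted p = 0.0263; adjusted p = 0.997 with an estimated correlation). Its members with the largest differences were Actc1, the cardiac alpha-actin gene, at 0.44, Mylpf, a myosin light chain gene, at 0.44, and Myh8, a myosin heavy chain gene, at 0.37. Of 19 cholesterol biosynthesis genes, 0 were higher or lower, also when adjusted over the list alone, and the list was higher (median 0.09, camera adjusted p = 0.0496; adjusted p = 0.997 with an estimated correlation). Examples were Mvd at 0.29 and Ebp at 0.25. Without the treated and the control array numbered 5, a choice made after seeing the data, both lists had an adjusted p of 0.455. With the replicate number as a block, the camera adjusted p was 0.000586 for muscle and 0.00615 for cholesterol genes. It was 0.851 for each with an estimated correlation.

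For the other lists, 0 members passed, also when adjusted over the list alone, and the adjusted p lay between 0.133 and 0.996. The median difference was 0.04 over 22 genes of midbrain dopaminergic identity and dopamine handling (adjusted p = 0.954), -0.02 over 12 genes enriched in substantia nigra neurons (0.828) and -0.01 over 13 genes enriched in the ventral tegmental area (0.954). It was 0.02 over 17 feedback and target genes of Wnt/beta-catenin signalling (0.797), among them Dkk1 at 0.14 and Nkd1 at -0.13, and 0.0050 over 37 genes of Wnt ligands, receptors and secreted antagonists (0.403), among them Sfrp4 at -0.55. The sign of the median, the mean or the test differed for the lists of ventral tegmental area genes, Wnt targets, Wnt components, proliferation, synaptic genes, axon guidance, familial parkinsonism, GABAergic and glutamatergic neurons, microglia and endoderm.

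Similarity to primary neurons was compared over all 19938 genes. The correlation across genes with the mean of the primary samples was 0.846 ± 0.017 (SD, n = 5) for treated and 0.843 ± 0.013 (n = 5) for control neurons, a difference of 0.0027 (exact permutation p = 0.762, two-sided, smallest possible 0.00794). Without treated array 5 the difference was -0.0040 and without control array 4 it was -0.00044, so its sign changed, and without control array 5 it was 0.0082. For genes that differed at least 2-fold between control and primary neurons, the median shift toward primary levels with treatment was -0.0067, without a test. It was -0.055 to 0.062 over 10 splits of the controls, and 48.3% of the genes moved toward primary levels. The shift of the 5 treated arrays was -0.0072, -0.030, -0.069, -0.13 and, for array 5, 0.22. Their SD was 0.13, so a small shift in either direction is not excluded.

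The second comparison set control iPSC-derived neurons against primary neurons of the same reporter line. In control iPSC-derived neurons, 18 of 22 dopaminergic identity genes and 25 of 28 synaptic and mature neuronal genes were lower, while 20 of 22 mesenchyme genes, 12 of 14 astrocyte and radial glia genes and 18 of 22 hypoxia genes were higher. As lists, these passed with the preset correlation of camera and were lost with an estimated correlation with all arrays (smallest adjusted p = 0.204 with an estimated correlation). Without the arrays numbered 5, a choice made after seeing the data, the dopaminergic identity and synaptic lists passed that way too (adjusted p = 0.0155 with an estimated correlation for each), and the other 31 lists did not. Those arrays stood apart by high levels of these same lists, so leaving them out favours both calls and is not independent support. Th was at 6.33 ± 1.26 (SD, n = 5) in control neurons against 11.2 in primary neurons, a log2 difference of -4.90 (SE 0.99, adjusted p = 0.00175). Mt2, a metallothionein gene, was higher by 6.79 (SE 0.20, adjusted p = 5.4e-10), and Gja1, the connexin 43 gene of astrocytes and other cells, by 5.67 (SE 0.20). With limma, 3855 genes were higher and 4491 lower of 19938, and 2114 and 1577 of these by at least 2-fold. The median over all genes was -0.11, and list medians are given relative to it.

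Of 22 measured genes of midbrain dopaminergic identity, 18 were lower, 3 higher and 1 did not pass. Adjusted over the list alone, the counts were 18 and 3. The list median was -2.92 relative to all genes (camera adjusted p = 0.00011; adjusted p = 0.323 with an estimated correlation). Besides Th, the list includes Slc18a2 (-4.70, SE 0.87), Nr4a2 (-4.31, SE 0.58), En1 (-3.29, SE 0.46), a homeobox gene of the midbrain, Foxa2 (-2.80, SE 0.33) and Pitx3 (-1.58, SE 0.18), the sort reporter's own locus, all lower in control iPSC-derived neurons. The 3 higher genes were Maoa (1.21), Maob (0.95) and Qdpr (0.53), which encode the monoamine oxidases and a pterin reductase. Control array 5 stood apart in this group: Th was at 8.52 on it and at most 6.17 on the other 4 control arrays, and Slc6a3 at 8.44 against at most 5.27. Slc6a3 was lower by a log2 difference of -3.18 (SE 1.11, adjusted p = 0.0367) with all arrays and of -3.85 (SE 0.14, adjusted p = 9.3e-09) without the arrays numbered 5. Its call was lost in 6 of 20 alternatives (adjusted p from 9.3e-09 to 0.167). Aldh1a1, a retinaldehyde dehydrogenase gene of substantia nigra neurons, was at -2.41 (SE 0.91, adjusted p = 0.0499) and lost its call in 12 of 20 alternatives (adjusted p from 2.2e-05 to 0.306). Without control array 5 its mean level was 6.64 ± 0.31 (SD, n = 4), against 9.52 in primary neurons.

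Of 13 genes enriched in the ventral tegmental area, 11 were lower and 2 did not pass, and 11 were lower and 1 higher when adjusted over the list alone. The list median was -1.30 (adjusted p = 0.000775; adjusted p = 0.204 with an estimated correlation). Examples were Cck, a neuropeptide gene, at -4.60 and Slc17a6, a vesicular glutamate transporter gene, at -4.10. Calb1 was lower at -1.41 (SE 0.36), but not against E13.5 alone (adjusted p = 0.160, with 0.00052 to 0.160 over 19 alternatives). Otx2 was lower at -0.96 (SE 0.25), but lost its call in 2 of 20 alternatives, among them E14.5 alone (adjusted p = 0.0977, with 0.00024 to 0.0977 over all 20). Of 12 genes enriched in substantia nigra neurons, 4 were lower, 1 higher and 7 did not pass, with 3 and 1 when adjusted over the list alone, and the list did not pass (median -0.16, adjusted p = 0.375). Its members with the largest differences were Anxa1 (5.23), Lmo3 (-3.19) and Satb1 (-2.60), and Sox6 did not pass (-0.19, SE 0.21, adjusted p = 0.463).

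Of 28 synaptic and mature neuronal genes, 25 were lower and 3 did not pass, with 25 lower when adjusted over the list alone. The list median was -1.94 (adjusted p = 8.2e-09; adjusted p = 0.204 with an estimated correlation). Examples were Syt4, a synaptotagmin gene, at -4.77, Nefm, a neurofilament gene, at -4.55 and Gria2, an AMPA receptor gene, at -4.34. Of 32 axon guidance and adhesion genes, 19 were lower and 5 higher, with 20 and 6 when adjusted over the list alone (median -1.05, adjusted p = 0.00250; adjusted p = 0.459 with an estimated correlation). Among them were the netrin receptor gene Dcc at -4.57 and L1cam at -3.70. Of 10 GABAergic neuron genes 7 were lower, with 7 over the list alone (median -0.59, adjusted p = 0.0086; adjusted p = 0.323 with an estimated correlation). Of 8 glutamatergic neuron genes 3 were lower, with 5 when adjusted over the list alone (median -0.30, adjusted p = 0.0327; adjusted p = 0.204 with an estimated correlation), a call lost without the 25% of genes with the lowest levels. The genes with the largest decreases were Slc10a4 (-5.67, SE 0.72), Kcnk9 (-5.40), Rab3c (-5.23), En2 (-4.94), Th, Dcx (-4.88) and Cbln1 (-4.84), together with the neuronal intermediate filament gene Ina. Dcx encodes a microtubule protein of young neurons.

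**Figure D2:**
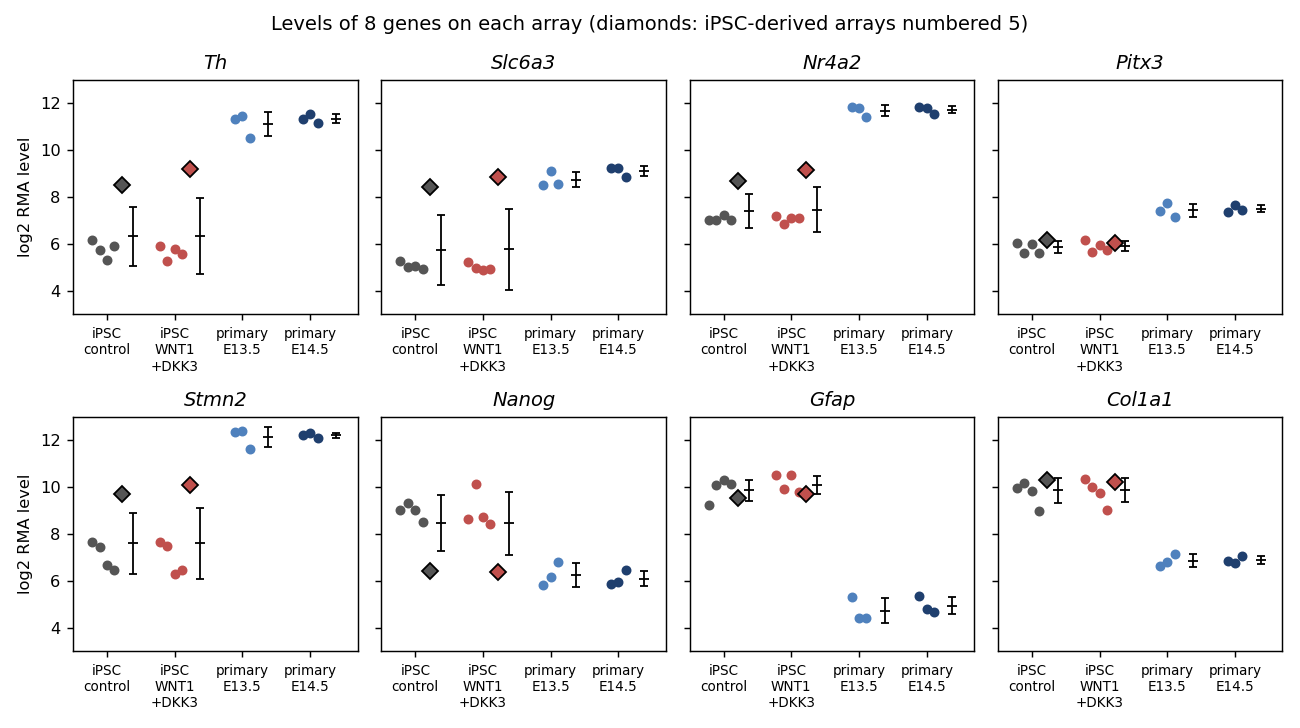
Log2 RMA level of 8 genes on each of the 16 arrays, by group, with the mean and SD of each group beside its points (for the primary groups the SD is over technical arrays). Th, Slc6a3, Nr4a2 and Stmn2 were higher and Nanog lower on the iPSC-derived arrays numbered 5 (diamonds) than on the other 4 arrays of their group, while Gfap and Col1a1 were above the primary levels on all 10 iPSC-derived arrays.

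Of 22 fibroblast, mesenchyme and stromal genes, 20 were higher and 2 did not pass, with 21 higher when adjusted over the list alone. The list median was 2.81 relative to all genes (adjusted p = 5.9e-12; adjusted p = 0.204 with an estimated correlation). Examples were the proteoglycan genes Dcn (5.68, SE 0.28) and Lum (5.09) and the matrix gene Postn (5.16). Of 14 astrocyte and radial glia genes, 12 were higher and 1 lower, with 12 and 1 when adjusted over the list alone (median 2.34, adjusted p = 8.8e-07; adjusted p = 0.204 with an estimated correlation). Gfap, the glial intermediate filament gene, was at 9.87 ± 0.45 (SD, n = 5) in control iPSC-derived neurons against 4.84 in primary neurons, a log2 difference of 5.03 (SE 0.30, adjusted p = 1.3e-07). Of 16 surface ectoderm and epithelial genes, 8 were higher and 8 did not pass, with 10 higher over the list alone and 13 of 16 higher without the arrays numbered 5 (median 1.97, adjusted p = 0.000466; adjusted p = 0.518 with an estimated correlation). The keratin gene Krt19 was at 5.24 (SE 0.63) and the cadherin gene Cdh1 at 3.51. Of 13 endothelial genes 4 were higher and 1 lower, with 5 and 1 when adjusted over the list alone, among them Cdh5 (3.27) and Flt1 (2.26), and the list call (median 0.71, adjusted p = 0.0482; adjusted p = 0.204 with an estimated correlation) was lost under quantile normalization and without the 25% of genes with the lowest levels.

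Of 22 genes of the hypoxia response and glycolysis, 18 were higher and 4 did not pass, with 18 over the list alone (median 2.09, adjusted p = 1.4e-10; adjusted p = 0.204 with an estimated correlation). Among them were the glucose transporter gene Slc2a1 (3.60) and the prolyl hydroxylase gene P4ha2 (3.39). Of 29 proliferation and DNA replication genes, 17 were higher and 12 did not pass, with 17 over the list alone (median 1.65, adjusted p = 3.5e-05; adjusted p = 0.556 with an estimated correlation). On control array 5 the median level of these genes was 5.98, against at least 7.55 on the other 4, and without the arrays numbered 5 all 29 were higher. Of 24 immediate early and stress genes, 12 were higher and 4 lower, with 12 and 5 over the list alone (median 0.80, adjusted p = 0.0135; adjusted p = 0.373 with an estimated correlation). Among them were the heat shock gene Hspb1 (4.89) and Ier3 (3.71). Of 19 cholesterol biosynthesis genes, 17 were lower and 2 did not pass, with 17 over the list alone (median -1.09, adjusted p = 6.2e-06; adjusted p = 0.204 with an estimated correlation). Examples were Idi1 at -2.47 and Hmgcs1 at -1.89. The genes with the largest increases were Mt2, Ifitm3 (6.75, SE 0.33), Ttr (6.67), S100a6 (6.59), Dcn, Krt18 (5.68), Gja1 and Ogn (5.65). Ifitm3 is interferon-inducible, Ttr encodes transthyretin and Krt18 a keratin.

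Of 37 genes of Wnt ligands, receptors and secreted antagonists, 14 were higher and 5 lower, with 14 and 5 over the list alone (median 0.32, adjusted p = 0.0156; adjusted p = 0.204 with an estimated correlation). Among them were Kremen1 (1.98), Wnt8b (1.82) and Sfrp1 (1.70). Of 17 Wnt target genes, 6 were higher and 1 lower, with 6 and 1 over the list alone, and the list did not pass (median 0.26, adjusted p = 0.0816). Axin2 was higher by 1.23 (SE 0.19), Ccnd1, the cyclin D1 gene, by 2.15 and Fzd7, a Wnt receptor gene, by 1.87. Dkk3 was higher by 1.05 (SE 0.24, adjusted p = 0.00458), a call lost against E14.5 alone (adjusted p = 0.0554, with 4.8e-05 to 0.0554 over 20 alternatives). Wnt1 did not pass (-0.22, SE 0.11, adjusted p = 0.134), but was lower once arrays were centred on their medians (adjusted p = 0.0115, with 0.0115 to 0.912 over 19). Its mean was 4.38 at E13.5 and 4.22 at E14.5, below the lower quartile of each primary array (4.57 or more), so these values may be background. The calls of the Wnt component and stress lists were lost under quantile normalization and without the 25% of genes with the lowest levels.

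Of 15 pluripotency genes, 0 were higher and 1 lower, with 0 over the list alone, and the list did not pass (median 0.75, adjusted p = 0.0509). Nanog, a transcription factor of pluripotent cells, was at 8.47 ± 1.18 (SD, n = 5) in control iPSC-derived neurons, with 6.42 on array 5 and 8.52 to 9.32 on the other 4, and at 6.18 in primary neurons. Without the arrays numbered 5, 9 of the 15 genes were higher and 0 lower and the list, with a median of 0.99, passed with the preset correlation (adjusted p = 0.395 with an estimated correlation). Dppa5a was then higher by 3.77 (SE 0.51), against a value of 2.94 (SE 1.43) that did not pass with all arrays. Pluripotency genes were low on the arrays left out, so the choice favours these calls. Of 21 midbrain progenitor genes, 12 were higher and 5 lower, with 12 and 5 over the list alone, and the list did not pass (median 0.92, adjusted p = 0.0539), among them Id3 (3.38), Slc1a3 (3.06) and Hes1 (2.56). Of 14 microglia and macrophage genes 8 were lower and 2 higher, with 9 and 2 over the list alone (median -0.33, adjusted p = 0.0975), with Cd68 at 3.09 and C1qb at -1.34. Of 16 endoderm genes 4 were higher and 1 lower, with 4 and 1 over the list alone (median 0.32, adjusted p = 0.0509), among them Krt18, Ttr and Krt8 (3.92). Of 28 muscle genes 5 were higher, with 4 over the list alone (median 0.33, adjusted p = 0.0609). The endoderm and progenitor lists passed without the arrays numbered 5 at the preset correlation (adjusted p = 0.456 and adjusted p = 0.395 with an estimated correlation).

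The other lists did not pass. The median relative to all genes was -0.17 for 17 forebrain genes (0 higher, 6 lower, adjusted p = 0.0816), -0.31 for 7 erythroid genes (0 higher, 3 lower, 0.0509), -0.16 for 6 serotonergic neuron genes (0 higher, 3 lower, 0.375). It was -0.11 for 10 cranial motor and cholinergic neuron genes (0 higher, 2 lower, 0.313). It was 0.22 for 31 oxidative phosphorylation genes (8 higher, 3 lower, 0.122), 0.018 for 17 neurotrophic factor and receptor genes (4 higher, 4 lower, 0.617), 0.068 for 10 genes of familial parkinsonism (3 higher, 4 lower, 0.654) and 0.046 for 20 Hox and hindbrain genes (1 higher, 0 lower, 0.815). It was 0.091 for 11 oligodendrocyte genes (3 higher, 2 lower, 0.455), -0.019 for 22 lens genes (1 higher, 3 lower, 0.481) and 0.11 for 10 neural crest genes (2 higher, 0 lower, 0.455). Adjusted over the list alone, 6 forebrain, 6 erythroid, 3 serotonergic and 0 motor neuron genes were lower. Also over the list alone, 8 oxidative phosphorylation genes were higher and 3 lower, 4 trophic factor genes were higher and 4 lower, 4 parkinsonism genes were higher and 4 lower. In the same way, 0 Hox genes, 3 oligodendrocyte, 1 lens and 2 neural crest genes were higher, and 2 oligodendrocyte genes and 0 lens genes were lower. Igf2, of the trophic list, was higher by 5.63 (SE 0.19). The sign of the median relative to all genes turned under quantile normalization for the trophic factor, parkinsonism and neural crest lists, and the median and mean relative to all genes or the test differed in sign for the parkinsonism, Hox, serotonergic and lens lists. In treated against primary neurons they differed for the lens and neural crest lists.

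The fit against primary neurons rests on 2 primary samples, 1 per stage, and the labels record no batch, so a contribution of array batch cannot be told apart from the group. Against E13.5 alone 2847 genes were lower and against E14.5 alone 2743. Centring each array on its median moved the median of all genes by -0.19 and gave 3046 genes higher and 8833 lower, 25.6% higher against 46.2% without it. By at least 2-fold, centred arrays gave 1690 higher and 1977 lower, so the direction with more genes depended on the scaling.

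The third comparison set treated neurons against primary neurons. In treated neurons, 18 of 22 dopaminergic identity genes and 23 of 28 synaptic and mature neuronal genes were lower, and 20 of 22 mesenchyme genes and 11 of 14 astrocyte and radial glia genes were higher. As lists, these were lost with an estimated correlation with all arrays (smallest adjusted p = 0.213 with an estimated correlation). Without the arrays numbered 5 the dopaminergic identity and synaptic lists passed that way too (adjusted p = 0.0143 with an estimated correlation for each), and the other 31 did not. Here too, the arrays left out stood apart by these same lists, so both calls are favoured by the choice. Th was lower by a log2 difference of -4.87 (SE 0.99, adjusted p = 0.00184). Without the arrays numbered 5 its difference was -5.59 (SE 0.23). Nr4a2 was lower by -4.24 (SE 0.58) and Foxa2 by -2.67 (SE 0.33). Mt2 was higher by 6.95 (SE 0.20, adjusted p = 5.2e-10), Gfap by 5.26 (SE 0.30) and the fibronectin gene Fn1 by 4.91 (SE 0.12). With limma, 3960 genes were higher and 4241 lower of 19938, of which 2123 and 1524 by at least 2-fold. Both comparisons share the primary samples, and the test of their difference in the same fit, treated minus control, gave 0 genes (smallest adjusted p = 0.522, 343 genes at an unadjusted p under 0.05).

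Of 22 dopaminergic identity genes, 18 were lower and 4 higher, with 18 and 4 when adjusted over the list alone (median -2.82 relative to all genes, adjusted p = 9.9e-05; adjusted p = 0.317 with an estimated correlation). Slc6a3 (-3.14, SE 1.11, adjusted p = 0.0387) and Aldh1a1 (-2.47, SE 0.91, adjusted p = 0.0455) were lower with all arrays, but lost their calls in 6 and 11 of 20 alternatives (adjusted p from 8.2e-09 to 0.175 and from 1.2e-05 to 0.294). On treated array 5, Th was at 9.22 and Slc6a3 at 8.87, against at most 5.93 and 5.22 on the other 4 treated arrays. Of 28 synaptic and mature neuronal genes 23 were lower and 5 did not pass, with 25 over the list alone (median -1.85, adjusted p = 3.6e-09; adjusted p = 0.213 with an estimated correlation). Among them were Syt4 (-4.79) and Nefm (-4.33). Of 22 mesenchyme genes 20 were higher, with 21 over the list alone (median 2.66, adjusted p = 2.4e-11; adjusted p = 0.213 with an estimated correlation). Among them were Dcn (5.48) and Postn (4.96). Of 14 astrocyte genes 11 were higher and 1 lower, with 13 and 1 over the list alone (median 2.48, adjusted p = 6.1e-07; adjusted p = 0.213 with an estimated correlation). Of 29 proliferation genes 16 were higher, with 20 over the list alone and 29 without the arrays numbered 5 (median 1.75, adjusted p = 3.4e-05; adjusted p = 0.553 with an estimated correlation).

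In this comparison 17 of 33 lists passed with all arrays, 0 of them with an estimated correlation, where the smallest adjusted p was 0.213. The pluripotency list passed here (0 of 15 genes higher or lower, also when adjusted over the list alone, median 1.08, adjusted p = 0.0395; adjusted p = 0.636 with an estimated correlation). So did the progenitor list (11 higher and 5 lower of 21, with 12 and 5 over the list alone, adjusted p = 0.0455; adjusted p = 0.438 with an estimated correlation). The muscle list passed as well (8 higher of 28, with 4 over the list alone, adjusted p = 0.0189; adjusted p = 0.553 with an estimated correlation). All of these 3 calls were lost without the 25% of genes with the lowest levels, and the first 2 also under quantile normalization. Wnt component genes were higher as a list (13 higher and 4 lower of 37, with 13 and 4 over the list alone, adjusted p = 0.0256; adjusted p = 0.213 with an estimated correlation), a call lost under both of these settings. Axin2 was higher by 1.11 (SE 0.19), Dkk3 by 1.13 (SE 0.24) and Ccnd1 by 2.22 (SE 0.28). The largest increases were those of Mt2, Ttr (6.78), Ifitm3 (6.68), S100a6 (6.58), Gja1 (5.61), Gsta4 (5.58), Igf2 (5.58) and Lgals3bp (5.56). The largest decreases were those of Kcnk9 (-5.42), Rab3c (-5.25), Slc10a4 (-5.16), Dcx (-4.99), En2 (-4.88), Th, Syt4 and Ina (-4.67). Against E13.5 alone 2722 genes were lower and against E14.5 alone 2622, and with centred arrays 3059 were higher and 8787 lower. By at least 2-fold, centred arrays gave 1654 higher and 1977 lower, against 2123 and 1524 without centring.

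**Figure D3:**
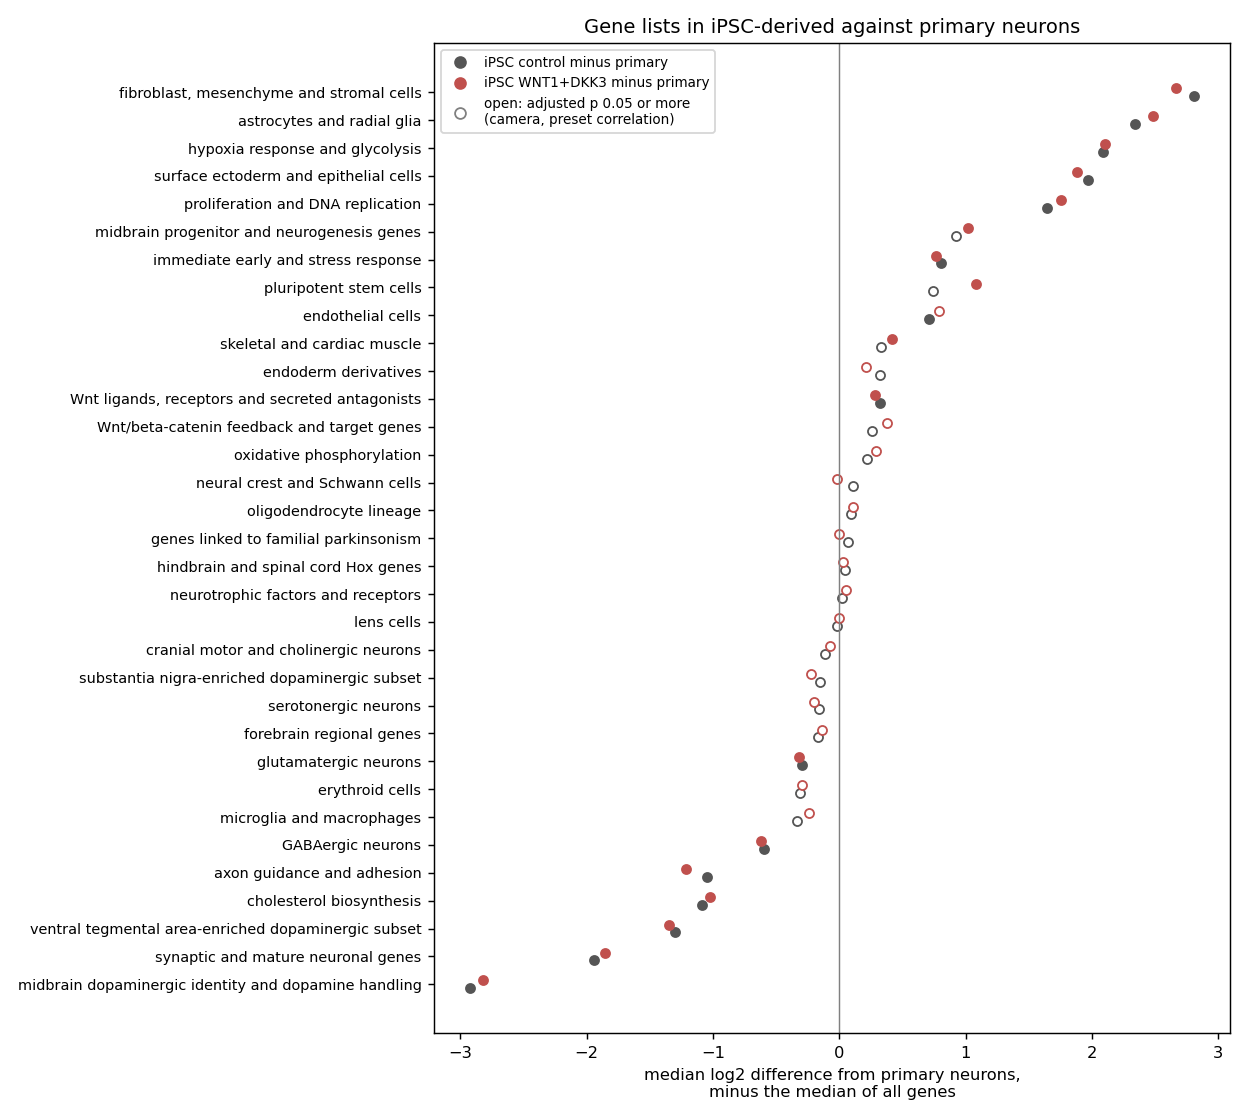
Median log2 difference of each of the 33 planned gene lists from primary neurons, minus the median of all genes, for control iPSC-derived neurons and for neurons differentiated with WNT1 and DKK3. Mesenchyme (2.81 and 2.66) and astrocyte genes (2.34 and 2.48) lay highest among these 33 lists and dopaminergic identity genes lowest (-2.92 and -2.82); filled points mark lists past the threshold of camera with the preset correlation, all of which were lost with an estimated correlation when all arrays were used.

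The last comparison set primary neurons of E14.5 against E13.5, with 1 sample per stage and therefore no test. A small number of genes differed by the rule used, among them Aldh1a1, Calb1 and Neurod6, which mark dopaminergic subtypes, and Lhx9 and Gli3, which encode patterning transcription factors. Aldh1a1 was at 10.19 ± 0.21 (SD over 3 technical arrays) at E14.5 and 8.85 ± 0.19 at E13.5, and Calb1 at 6.46 ± 0.19 and 5.28 ± 0.92. By the rule of at least 2-fold and no overlap of the arrays, 35 genes were higher and 13 lower at E14.5, while in simulated data the same rule called 59 unchanged genes, so any of these genes can be a chance call. Without a size limit 9.68% of genes did not overlap, where chance gives 10%. Among genes counted as higher, the largest differences were those of Tafa1 (1.67), Ccl3 (1.59), a chemokine gene, Neurod6 (1.47), a transcription factor of ventral tegmental neurons, Ndrg2 (1.46), Selenop (1.46), Ctss (1.43), a protease gene of microglia, Il1a (1.35) and Rsph4a (1.35). Among those counted as lower, they were those of Lhx9 (-1.52), Mab21l2 (-1.50), Gli3 (-1.36), Zfp626 (-1.31), Rnf24 (-1.18), Tfap2d (-1.15), Mcur1 (-1.11) and Zfp418 (-1.11). Th (0.23), Pitx3 (0.07), Nr4a2 (0.04), Slc6a3 (0.37) and Slc18a2 (-0.46) were not counted as different.

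Set against 10000 random lists of the same size and mean expression, the median of 14 microglia genes (0.43) and of 24 stress genes (0.28) lay at the 100th percentile, although only 2 microglia and 2 stress genes counted as higher, with the complement gene C1qc at 1.01 and the immediate early genes Fos at 1.14 and Egr1 at 1.09. Oxidative phosphorylation genes (median 0.21) lay at percentile 99.98, astrocyte genes (0.25) at 99.95, substantia nigra genes (0.21) at 99.69 and glutamatergic neuron genes (0.23) at 99.51. GABAergic neuron genes (-0.33, with Gata3 at -0.92 and Sox14 at -0.85) lay at percentile 0, dopaminergic identity genes (-0.08) at 0.84, epithelial genes (-0.15) at 1.67 and forebrain genes (-0.15) at 2.26. The other lists lay between percentiles 4.16 and 85.4. These percentiles describe the 2 samples, and leaving out 1 technical array at a time, which makes the rule easier to meet, gave 49 to 70 genes higher and 19 to 38 lower. Random lists hold independently drawn genes, so percentiles of lists whose members vary together can be too extreme. The median level of dopaminergic identity genes was instead higher on every E14.5 array (9.28 to 9.43) than at E13.5 (8.74 to 9.24). Array medians of the stages overlapped for the stress, oxidative phosphorylation and astrocyte lists, but not for the microglia, GABAergic, glutamatergic and substantia nigra lists.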

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

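The tests of the arrays numbered 5 and of the difference between iPSC-derived and primary neurons were chosen after the results were seen, and some were revised after their values were known; the counts of other splits were planned.

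In groups of 5 arrays, an array was singled out where its gap to the nearest other array was more than 0.71 of the group's range. Of 96 groups (a gene or list within treated or control arrays), 22 held such an array, where chance gives about 1 in 20 groups, or 4.8, and the groups are not independent. All 22 were the array numbered 5. Th was at 9.22 on treated array 5 (nearest other 5.93) and 8.52 on control array 5 (6.17), Slc6a3 at 8.87 (5.22) and 8.44 (5.27), and Slc18a2 at 8.25 (5.28) and 7.44 (5.52). Nr4a2 was at 9.16 (7.18) and 8.67 (7.24), En1 at 7.29 (5.91) and 7.13 (5.91), and Aldh1a1 at 9.64 (6.67) and 8.985 (6.99). Calb1 was at 5.305 on treated array 5 (4.31). The median level of dopaminergic identity genes was 7.47 on treated array 5 (6.27) and 7.35 on control array 5 (6.17). That of synaptic genes was 6.56 (5.81) and 6.49 (5.90), and that of trophic factor genes 7.47 (6.68) and 7.285 (6.69), although the median shift of the trophic factor genes themselves was only -0.06 and 0.06. The median of ventral tegmental area genes was 5.685 on treated array 5 (4.84). On control array 5, the median of proliferation genes was lower, at 5.98 (7.55), and that of pluripotency genes as well, at 5.56 (7.10). Treated array 5 also lay below the other 4 treated arrays, at 6.09 (nearest other 7.325) and 5.39 (6.87), within the limit of the rule. Mesenchyme genes had a median shift of 0.57 on treated and 0.57 on control array 5, muscle genes of 0.63 and 0.33, and astrocyte genes of -0.59 and -0.49. Among 13767 probe sets outside the gene-level data, limma called 0 for treated against control.

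The first pattern weighed was that of the arrays numbered 5. Against RNA of primary neurons mixed in as the only cause stands that 66 of 253 genes at least 2-fold higher in treated array 5 than in the other 4 treated arrays, 26.1% (95% interval 20.8 to 32.0), had a primary level below the mean of those 4 arrays, and 29.4% (22.7 to 36.9) in control array 5. Against a lower share of pluripotent cells as the only cause stands that the synaptic median shift exceeded the astrocyte median shift by 1.42 (0.58 to 2.00) in treated and by 1.23 (0.61 to 1.78) in control array 5. This assumes that such a loss would raise the markers of other cell types alike, which was not tested. Mesenchyme genes rose by a median of 0.57 on both arrays, unlike astrocyte genes. All these intervals treat the genes of an array as independent and do not measure the spread between samples. A first version of these tests had pooled both arrays against the other 8 and gave the same verdicts, and a test of treated minus control array 5 was dropped because the labels do not say that equal numbers mark paired samples. A different culture or sort may be behind these arrays, which stays open. Beyond the share of pluripotent cells, no biological explanation was tested because the design names no difference between replicates.

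The second pattern was the difference between iPSC-derived and primary neurons, with 3855 genes higher and 4491 lower in control neurons. A contribution of array batches or amplifications cannot be told apart from the groups, because no batch is recorded. The deviation of treated array 5 from the other treated arrays was related to primary minus control across genes (r = 0.422, 0.402 to 0.443), and that of control array 5 to primary minus treated (r = 0.397), computed later. The first value lies above the bound of 0.1 first set and had been read as excluding batch as the only cause, but this reading was withdrawn after the value was known, and it stays withdrawn because the arrays numbered 5 may share a batch of their own. Cells other than dopaminergic neurons in the iPSC-derived samples are a candidate source: 32 of 36 mesenchyme and astrocyte markers, 88.9% (73.9 to 96.9), were higher in control iPSC-derived neurons, with Gfap at 9.87 and Col1a1 at 9.86. The interval treats markers as independent, 3 of the astrocyte markers stand in other lists too, and these values had been seen before the test. The design text says that cells were sorted for GFP, and how far this removed other cells was not measured. Pitx3, the reporter locus, was at 5.89 in control iPSC-derived and 7.47 in primary neurons.

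For treated against control, all 100 drawn splits of the 10 arrays, of 126 possible, gave at least as many genes as the real count of 0 with limma (300 genes at an unadjusted p under 0.05), which a count of 0 makes certain, so this number says nothing about chance. Of these splits 3 gave at least 1 gene, and the highest gave 909, with treated arrays 1, 2 and 5 and control arrays 2 and 5 against the rest. A split that calls many genes points to a structure of the samples. The 45 splits with both arrays numbered 5 on the same side reached 909 genes, and the others at most 1. For E14.5 against E13.5, 1 of 10 splits, the real one, gave as many genes as the real 48, the highest other split gave 34, and 10 splits are too few for a share under 0.05.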

How the results depend on the processing

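All alternatives were planned except leaving out both arrays numbered 5, which was chosen after seeing the data. For treated against control, 0 genes passed in limma (300 at an unadjusted p under 0.05) and in every alternative except the replicate number as a block, which gave 1 gene higher, Mir17, and 0 lower (834 at an unadjusted p under 0.05). The block also put mesenchyme genes, lower at a median of -0.07, past the threshold as a list (adjusted p = 0.00169; adjusted p = 0.851 with an estimated correlation). The muscle and cholesterol lists also passed with the block (camera adjusted p = 0.000586 and 0.00615, and 0.851 for each with an estimated correlation). The labels do not say what a number marks. Same-number correlations of deviations across genes were 0.045, 0.52, 0.44, 0.72 and 0.80, and 3 of 5 treated arrays correlated best with the control of their own number, so arrays 2 to 5 may share a source, but not every number pairs the samples and the fit without the block was kept. Where numbers do pair samples, this fit counts their shared spread as noise and can miss genes. For control against primary neurons, 2114 genes were higher and 1577 lower by at least 2-fold, 2847 were lower against E13.5 alone, 2743 against E14.5 alone and 8833 with centred arrays. For treated against primary neurons these counts were 2123, 1524, 2722, 2622 and 8787. The count of higher genes reached 4990 and 5053 with all 16 arrays and the sample as a random block. The correlation estimated for that block was -0.048, so technical arrays counted almost as separate samples, which raises the counts. A size limit or a single primary sample lowers counts by construction, and centring moves all genes. Leaving out 1 replicate gave 3566 to 4129 higher and 4028 to 4677 lower for control, and 3661 to 4290 and 3729 to 4455 for treated neurons. For E14.5 against E13.5, 207 genes were higher and 113 lower by at least 1.5-fold, and without 1 technical array 49 to 70 were higher and 19 to 38 lower, since fewer arrays overlap less.

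The treated minus control difference in similarity was 0.0014 to 0.0099 over 8 alternatives, and the shift toward primary neurons -0.0078 to 0.040 over 7. Over named genes and alternatives, control against primary lost 104 calls, gained 35 and had 2190 the same, and treated against primary lost 100, gained 29 and had 2202 the same. Lists lost 22 and gained 3 calls for control, lost 27 and gained 1 for treated neurons, and lost 4 and gained 1 for treated against control; the cause was not tested. Among values that did not pass, the sign changed in 85 for treated against control and in 1 for control against primary. No detection call limits dim genes, so their values may be background: without the 25% of genes with the lowest levels, 157 genes had an unadjusted p under 0.05 for treated against control, and limma called 0.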

Other observations

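All tests of the added lists and the choice of Mir17 were made after seeing the data. Interferon-stimulated genes, which respond to viral RNA or interferon, were higher in control iPSC-derived than in primary neurons: 21 of 22 measured genes were higher and 1 did not pass, with 21 when adjusted over the list alone. The list median was 3.19 relative to all genes (camera adjusted p = 1.1e-13; adjusted p = 0.203 with an estimated correlation), with Ifitm3 at 6.75, Ifit3 at 5.33 and Oasl2 at 4.51. Of 21 trophoblast and placenta genes, 13 were higher and 8 did not pass, with 14 over the list alone (median 2.89, adjusted p = 3.2e-05; adjusted p = 0.417 with an estimated correlation), among them Rhox9 at 5.25, Plac8 at 4.99 and Ctsj at 4.68. Of 14 choroid plexus genes, 10 were higher and 4 did not pass, with 10 over the list alone (median 2.21, adjusted p = 4.2e-05; adjusted p = 0.302 with an estimated correlation), among them Ttr at 6.67, Ecrg4 at 5.23 and Wfdc2 at 3.65. Ttr stands in the endoderm list as well. The lists were chosen because some of these genes were among those with the largest increases, so their counts are not independent evidence.

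In treated against primary neurons, 20 interferon-stimulated genes (median 3.19, adjusted p = 8.6e-13; adjusted p = 0.211 with an estimated correlation), 10 trophoblast genes (median 2.62, adjusted p = 0.00036; adjusted p = 0.466 with an estimated correlation) and 10 choroid plexus genes (median 2.05, adjusted p = 3.9e-05; adjusted p = 0.287 with an estimated correlation) were higher, with 21, 10 and 10 when adjusted over the list alone. In treated against control neurons 0 genes of these lists passed, also when adjusted over the list alone. The trophoblast list was lower (median -0.20, adjusted p = 0.00324; adjusted p = 0.997 with an estimated correlation) and the interferon list was lower (median -0.09, adjusted p = 0.0302; adjusted p = 0.997 with an estimated correlation), and the choroid plexus list did not pass (median 0.06, adjusted p = 0.892). Mir17, the gene with the smallest adjusted p (0.753) in treated against control neurons, had a level of 5.88 ± 0.20 (SD, n = 5) in treated and 4.93 ± 0.28 in control neurons, a log2 difference of 0.95. It was higher in all 5 treated arrays than in any control array. Prl7a1, a prolactin family gene, had the largest difference, -1.19 (SE 0.57), and did not pass.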
